A study of Mus musculus with 8 samples.

How the data were processed

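RNA was measured in microglia from the brains of wild-type mice aged 4 or 21 months, from white matter, which is the corpus callosum, and from grey matter. Per the series' design text and the labels' protocols, myelin was removed on a Percoll gradient, the cells were drawn from the suspension with magnetic beads against CD11b, a surface protein of microglia and other myeloid cells, and polyadenylated RNA was sequenced on an Ion Proton instrument. The 8 libraries form 4 groups of 2, by region and age, as the sample titles give them. The labels also name the corpus callosum as the region of the grey matter samples, so the split into white and grey matter rests on the titles and the tissue label. Nothing states that the 2 libraries of a group came from separate animals. The p-values of single genes therefore measure the spread between these samples, which may be technical.

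The deposited count table holds estimated counts per gene, with symbols as gene names and values that are mostly whole; between 17.9% and 19.7% of the values above 0 in a library were not whole. The authors named Partek and DESeq2, with no version or role, per the submitters' processing notes. The aligner, genome build, annotation and use of strand are not given in the sources used here, so no coordinates are given, and reads shared by near-identical genes cannot be assigned. A second deposited table holds a normalised signal for 18448 of the 51810 genes. In it every value equals the rounded count times 1 factor per library within 1e-06 of its size, for 100% of the values with a count, as size factors give. That table was used in 1 alternative. Another deposited file repeats barcode, region and age and was not used.

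The estimated counts were rounded to whole numbers. Library totals ran from 3273258 to 6315782 counts. Every line of the table carried a gene name, and 18945 genes had no count in any library. The 37 mitochondrially encoded genes of the table had a count of 0 in all libraries, so that list was not tested. Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 16237, and libraries were scaled by TMM. The 4 group means were fitted with edgeR's quasi-likelihood model, robust, to all 8 libraries with 4 residual degrees of freedom. The 5 comparisons were white against grey matter at each age, 21 against 4 months in each region, and the difference between the aging changes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. The smallest two-sided exact permutation p for 2 libraries against 2 is 0.333, so single genes were tested only through these models.

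Of 31 gene lists fixed before the data were examined, those with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. At the preset correlation, camera weighs a list against the other genes, so its p mainly reflects the spread over genes and not that between libraries. The tests and the rule for named genes were set at the same time. By that rule, the text names the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean count of at least 50 in the highest group and no overlap between the libraries compared in log CPM. Predicted gene models, Xist and Y-linked genes were left out, and the overlap condition did not apply to the age by region comparison. The rule also names up to 4 called members of each list, and Apoe, Cst7, Clec7a, Itgax, Spp1, Axl, Lpl, P2ry12, Tmem119 and Cx3cr1 in every comparison. Because the fit of all 8 libraries called no gene, the rule was applied to the fit of the 21-month libraries alone, which was planned, and to the fit without the first 4-month white matter library. That use was chosen after the results were seen. Further examples, chosen after their values were seen, are named as such.

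On simulated counts made from these libraries for the 21-month comparison, the fit of all 8 libraries (16237 genes) recovered 0% of the genes changed by 1, 2 or 3 on the log2 scale. The fit without the first 4-month white matter library (17509 genes) recovered 7.46%, 79.1% and 93.9%. With the 21-month libraries alone (14717 genes), it recovered 37.3%, 88.1% and 98.5%. The changed genes, 67, 67 and 66 for the 3 sizes of change, were drawn from genes with a mean count of at least 50. The rates do not cover genes of lower count. Each simulation drew all its libraries with the dispersions of its own fit and no other difference between groups. The 0% thus holds for 21-month libraries given the wider spread of the fit of all 8, not their own. The common dispersion was 0.257 with all 8 libraries, 0.126 without that library and 0.0503 with the 21-month libraries alone.

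Further settings fixed at that time were DESeq2 1.42.0, RLE scaling, library size only, no low-count filter, at least 10 counts in every library, the replicate number as a block over all groups or within an age, each library left out in turn, limma on log2 of the deposited normalised values plus 1, only the 4 libraries compared, and a minimum absolute log2 fold change of 1. Voom with library quality weights and DESeq2 without the first 4-month white matter library were added after the data were seen.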

Results

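The series profiled microglia of white and grey matter from mice aged 4 and 21 months, with 2 libraries in each of the 4 groups. Its title puts the question of whether aging of white matter makes microglia more diverse. Totals were 4475574 and 3551010 counts in 4-month white matter, 6315782 and 4987199 in 4-month grey matter, 4241439 and 3506342 in 21-month white matter, and 4545028 and 3273258 in 21-month grey matter. Levels are in CPM, the share of a library's counts after TMM scaling.

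The first 4-month white matter library stood apart from the other 7. Its oligodendrocyte markers summed to 77940 CPM, against 599 to 1410 in the others. Mbp, a structural gene of myelin, reached 8228 CPM there and 136.2 in its partner. Its homeostatic microglia genes summed to 8775 CPM, against 27120 to 41270 in the other 7. Across genes, its correlation with any other library was 0.666 to 0.757, while the other 7 correlated at 0.853 to 0.969 with each other. The transcripts CT010467.1 and AY036118 took 38.8% of its counts and 6.78% to 20.7% of the counts of the others.

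**Figure D1:**
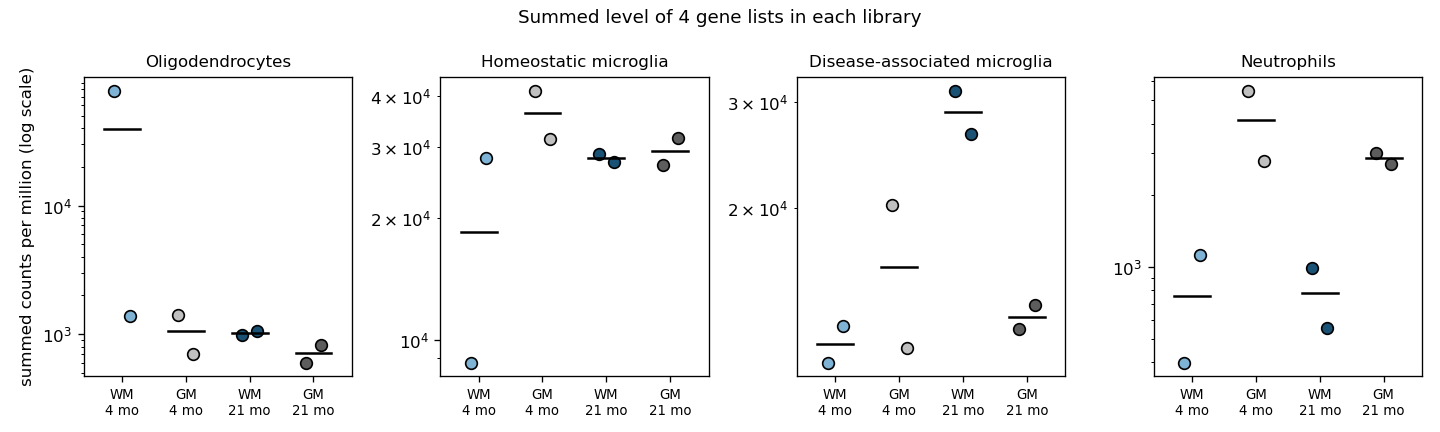
Summed level of 4 gene lists in each library, in TMM-scaled CPM on log axes that differ between panels; points are libraries, bars are arithmetic group means (n = 2), WM is white matter and GM grey matter. The oligodendrocyte sum of 77940 in 1 of the 4-month white matter libraries lies above the other 7, the 21-month white matter libraries have the highest disease-associated sums (31300 and 26510), and neutrophil sums are lower in every white matter library than in every grey matter library.

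White and grey matter were first compared at 21 months. Apoe, which carries lipids between cells, averaged 3813 ± 925 CPM (SD, n = 2) in white matter and 259.8 ± 17.7 in grey matter. Spp1, which encodes osteopontin, averaged 314 ± 48.6 and 4.71 ± 0.34. Lpl, a lipoprotein lipase, averaged 272.6 ± 55.4 and 8.06 ± 4.29, and Itgax, which encodes CD11c, 186.8 ± 44.6 and 23.3 ± 5.28. Lcn2, an iron-trafficking protein of neutrophils, averaged 20.04 ± 10.8 in white matter and 228.9 ± 29.2 in grey matter.

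In edgeR's quasi-likelihood test on all 8 libraries, 0 genes passed an adjusted p of 0.05 in this comparison, and 381 had an unadjusted p under 0.05. DESeq2 called 47, limma on the deposited normalised values 0 and limma with voom quality weights 123. The call depended on the 4-month libraries in the fit: leaving out the first 4-month white matter library gave 13 genes higher and 6 lower in white matter, leaving out the second gave 16, and the 21-month libraries alone gave 145 higher and 87 lower, which included all 19. In the 21-month fit, the largest rises were in Gpnmb, a glycoprotein of phagocytes, by 6.62 ± 0.64 (SE) on the log2 scale (adjusted p = 0.0118), in Spp1 by 6.03 ± 0.235 (adjusted p = 1.6e-06) and in Pianp by 5.12 ± 0.426 (adjusted p = 0.000454). Lpl rose by 5.02 ± 0.348, Apoe by 3.87 ± 0.23, Igf1, a growth factor, by 3.65 ± 0.247 and Itgax by 3.003 ± 0.237. Rai14, Lox, Pdcd1, Cxcl13 and Egln3 rose by 4.08 to 4.44. Cst7, a protease inhibitor, rose by 2.95 and Axl, a receptor that takes part in the uptake of dying cells, by 2.36. Clec7a differed by 2.48 (adjusted p = 0.423), P2ry12 by -0.57 (adjusted p = 0.159), Tmem119 by -0.40 (adjusted p = 0.415) and Cx3cr1 by -0.19 (adjusted p = 0.786), so these did not pass. Mmp12, Gas2l3 and Myo5a rose by 3.78, 2.60 and 2.02 in the fit without the first 4-month white matter library (adjusted p = 0.0424, 0.0234 and 0.0228).

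**Figure D2:**
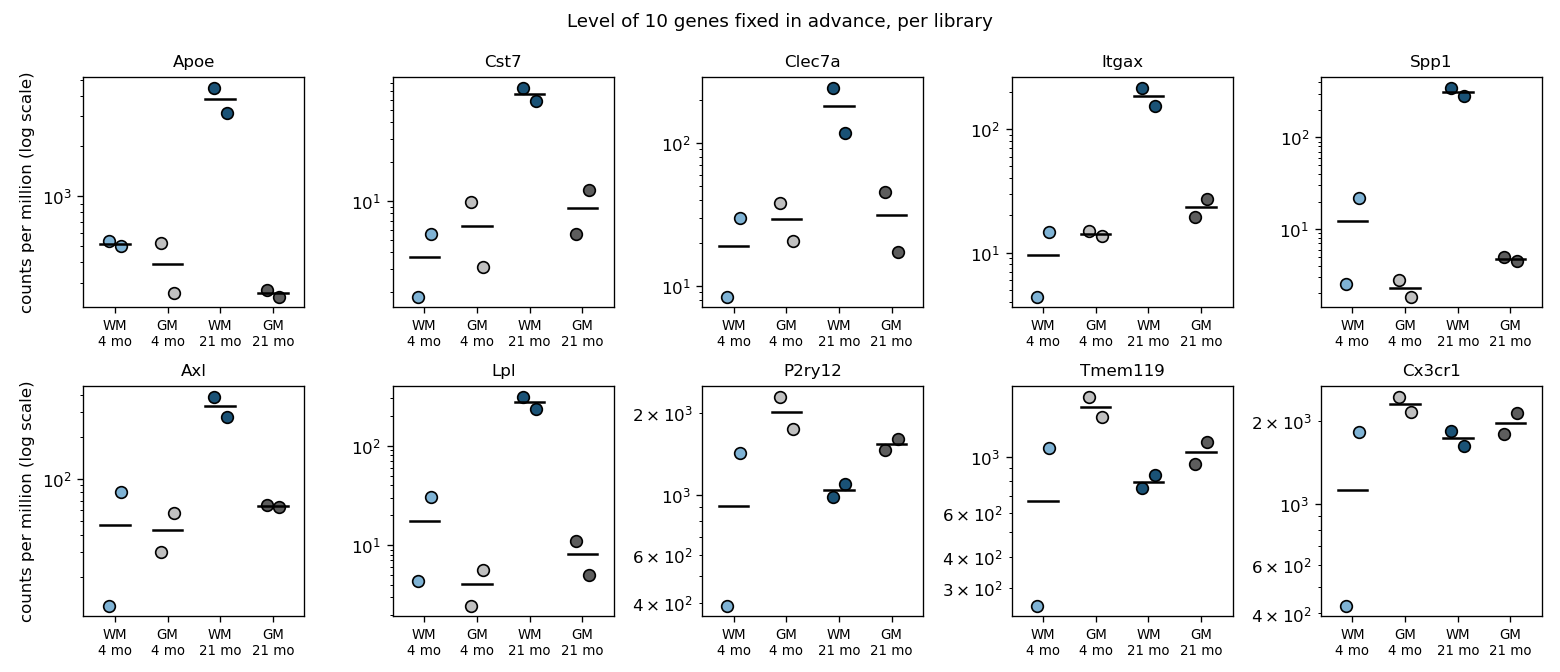
Level of 10 genes fixed in advance in each library, in TMM-scaled CPM on log axes that differ between panels; points are libraries and bars are arithmetic group means (n = 2), WM white matter and GM grey matter. Apoe, Cst7, Clec7a, Itgax, Spp1, Axl and Lpl lie highest in both 21-month white matter libraries (Apoe at 4468 and 3159), and P2ry12, Tmem119 and Cx3cr1 lie lowest in 1 library of 4-month white matter.

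All 30 genes of the disease-associated microglia list lay above 0 in this comparison, with a mean log2 fold change of 1.81 in the fit of all 8 libraries (camera adjusted p = 1.6e-42), and the adjusted p was 0.0912 with an estimated correlation. None of the 30 was called over all genes; adjusted over the list alone, 9 were. In the 21-month fit 15 of the 30 were called, and 28 adjusted over the list alone. Cholesterol efflux and lipid storage genes, a list that shares Apoe and Lpl with the former, had a mean of 1.40 with 19 of 20 above 0 (adjusted p = 3.71e-14, and adjusted p = 0.0824 with an estimated correlation), and 4 were called in the 21-month fit, and 11 adjusted over the list alone. Among these, Nceh1 and Lipa, which hydrolyse cholesterol esters, rose by 1.94 ± 0.229 and 0.98 ± 0.17. Inflammatory genes had a mean of 0.60 with 24 of 29 above 0 (adjusted p = 3.42e-08, and adjusted p = 0.47 with an estimated correlation); 8 were called in the 21-month fit, all higher, among them Tnf by 1.58, Cxcl16 by 1.47 and Ccl3 by 1.05. Lysosome genes had a mean of 0.50 with 36 of 42 above 0 (adjusted p = 1.43e-06, and adjusted p = 0.454 with an estimated correlation). This list shares Cd68, Ctsa, Ctsb, Ctsd, Ctsl and Ctsz with the disease-associated list. The proteases Ctsd and Ctsb rose by 1.18 and 0.97, and the proton pump subunit Atp6v0d2 by 4.27, in the 21-month fit. Of the 14 glycolysis genes 12 lay above 0, with a mean of 0.44 (adjusted p = 0.00131, and adjusted p = 0.375 with an estimated correlation). The glucose transporter Slc2a1 and the enzymes Pkm, Aldoa and Tpi1 rose by 0.87 to 1.23 in the 21-month fit. Homeostatic microglia genes had a mean of -0.22 with 8 of 25 above 0 (adjusted p = 0.0635). That list passed at -0.22, -0.21 and -0.29 when the first or the second 4-month white matter library or the first 21-month grey matter library was left out (adjusted p = 0.0012, 0.00169 and 0.0444); the adjusted p was then 0.471, 0.5 and 0.881 with an estimated correlation, and 0.817 with all 8 libraries. The inflammatory mean was 0.35 without the first 21-month white matter library (adjusted p = 0.00824, and adjusted p = 0.946 with an estimated correlation). Immediate early and heat shock genes had a mean of 0.09 with 14 of 26 above 0 in the 21-month fit, where Dusp2 rose by 1.49 (adjusted p = 0.0255). With all 8 libraries but the second of 21-month white matter, that list passed with a mean of 0.35 and 19 of 26 above 0 (adjusted p = 0.00469, and adjusted p = 0.716 with an estimated correlation). Among members of the lists called in the 21-month fit, Cox6a2 also rose by 3.14, Bcl2a1d by 1.99, Nes by 1.66 and Cd22 by 1.33. Cxcl10 rose by 1.28, Insig1 by 1.20, Cox6a1 by 0.97 and B2m by 0.87 there, while Hp, Cd24a and Vcan lay at -2.72, -2.54 and -2.13. Gda lay at -3.20 in the fit without the first 4-month white matter library.

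Markers of neutrophils, monocytes and border-associated macrophages were lower in white matter. All 12 neutrophil genes lay below 0, with a mean of -3.11 (adjusted p = 1.92e-53, and adjusted p = 0.0824 with an estimated correlation), and so did all 12 monocyte genes, with a mean of -2.13 (adjusted p = 1.95e-25, and adjusted p = 0.0798 with an estimated correlation). In the 21-month fit 5 neutrophil and 6 monocyte genes were called; adjusted over the list alone, 7 and 10 were. The log2 fold change was -3.27 for the protease Mmp8, -2.87 for Mmp9, -3.21 for the chemokine receptor Cxcr2, -3.52 for Lcn2 and -2.76 for the monocyte marker Ly6c2. The largest falls among the genes the rule names were those of Prg2 at -7.19 ± 0.705, Fcnb at -5.19 ± 0.81 and Elane, which encodes neutrophil elastase, at -4.91 ± 0.599. G0s2, Lrg1, Anxa1, Cd177, F10 and Asprv1 lay between -4.03 and -3.46. Border-associated macrophage genes had a mean of -1.23 with 11 of 12 below 0 (adjusted p = 5.91e-07, and adjusted p = 0.375 with an estimated correlation); F13a1 and Maf lay at -1.97 and -0.96 in the 21-month fit, where both were called. The 8 red blood cell genes also all lay below 0, with a mean of -1.82 (adjusted p = 0.000496, and adjusted p = 0.47 with an estimated correlation). Without the first 21-month grey matter library the red blood cell mean was -0.62 and did not pass (adjusted p = 0.142), and without the second 21-month white matter library the border-associated macrophage mean was -2.10 (adjusted p = 1.74e-08, and adjusted p = 0.389 with an estimated correlation). The red blood cell sums overlapped between the regions, at 753.6 and 203.6 CPM in white matter and 2667 and 736.3 in grey matter. Between libraries of the same replicate number, the sum was higher in grey matter each time. The choroid plexus gene Ttr stood at 9006 CPM in 1 of the 21-month white matter libraries and at 242.8 to 342.3 in the other 3 libraries of that age.

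At 4 months, white matter carried fewer neutrophil and monocyte transcripts than grey matter. A fall was not particular to these lists, since 19 of the 28 lists tested passed downward at the preset correlation with all 8 libraries. Border-associated macrophage markers, for 1, summed to 97.03 and 633.4 CPM in white matter and 1036 and 912.2 in grey matter. The 12 neutrophil genes had a mean log2 fold change of -2.73 and the 12 monocyte genes of -2.06, with all of them below 0 (camera adjusted p = 3.7e-20 and 1.5e-11, and adjusted p = 0.359 for both with an estimated correlation). These means were -2.23 and -2.001 without the first 4-month white matter library, again with all members below 0. Oligodendrocyte genes had a mean of 5.80 with all 16 above 0 (adjusted p = 9.09e-13, and adjusted p = 0.39 with an estimated correlation), and 0.75 without that library. Homeostatic microglia genes had a mean of -0.97 with 24 of 25 below 0 (adjusted p = 2.32e-10, and adjusted p = 0.43 with an estimated correlation), and -0.35 without that library and -2.26 without the second (adjusted p = 3.98e-05 and 5.19e-18, and adjusted p = 0.57 and 0.438 with an estimated correlation). Ependymal and choroid plexus genes had a mean of 3.77 (adjusted p = 8.14e-07, and adjusted p = 0.359 with an estimated correlation), and of 2.84 without the second white matter library, where the list did not pass (adjusted p = 0.119); Ttr stood at 1974 and 5269 CPM in white matter and at 171.1 and 17.6 in grey matter.

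No gene passed in edgeR's test at 4 months, where 1446 had an unadjusted p under 0.05, DESeq2 called 587 and both limma fits called 0. Leaving out the second 4-month white matter library, so that only the library with the myelin transcripts stood for the group, gave 4222 calls, and leaving out the first gave 0. Of the fixed genes, Spp1 differed by 2.41 ± 0.847 (adjusted p = 0.494) with all 8 libraries and by 3.24 ± 0.336 (adjusted p = 0.111) without the first, and Lpl by 2.11 and 2.91 (adjusted p = 0.554 and 0.92). Spp1 stood at 21.8 CPM in the second white matter library, 2.54 in the first, and 2.79 and 1.83 in grey matter. Apoe differed by 0.40, Cst7 by -0.77, Clec7a by -0.61, Itgax by -0.54, Axl by 0.11, P2ry12 by -1.16, Tmem119 by -1.24 and Cx3cr1 by -1.03, with adjusted p between 0.65 and 0.982 for these. In DESeq2 without the first library, only the second stood for 4-month white matter, and Spp1 rose by 3.27. The neutrophil genes Lcn2, Mmp9 and Cxcr2, examples chosen after their values were seen, had log2 fold changes of -2.86, -2.71 and -2.42 in that fit.

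Within white matter, disease-associated genes stood higher at 21 than at 4 months. Apoe averaged 3813 ± 925 CPM (SD, n = 2) at 21 months and 516.1 ± 23.1 at 4 months, and Itgax 186.8 ± 44.6 and 9.58 ± 7.38. Of the 30 disease-associated genes 28 lay above 0, with a mean log2 fold change of 1.97 (camera adjusted p = 2.27e-27, and adjusted p = 0.472 with an estimated correlation). Adjusted over the list alone, 14 were called, and none over all genes. Leaving out the first 4-month white matter library put all 30 above 0, with a mean of 1.67 and 19 called adjusted over the list alone. Interferon-stimulated genes had a mean of 1.28 with 31 of 33 above 0 (adjusted p = 1.93e-13, and adjusted p = 0.472 with an estimated correlation), and 0.81 without that library. MHC class I genes had a mean of 1.26 with all 16 above 0 (adjusted p = 9.88e-10, and adjusted p = 0.472 with an estimated correlation), and 0.65 without it. Vascular markers stood higher at 21 months as well. Pericyte and smooth muscle genes had a mean of 1.77 with all 11 above 0 (adjusted p = 1.76e-06, and adjusted p = 0.472 with an estimated correlation), and endothelial genes of 2.09 with all 14 above 0 (adjusted p = 7.28e-05, and adjusted p = 0.482 with an estimated correlation). The means were 0.87 and 1.38 without that library. Oligodendrocyte genes had a mean of -6.37 with all 16 below 0 (adjusted p = 1.82e-13, and adjusted p = 0.472 with an estimated correlation), and -1.30 without it. The homeostatic list changed sign, from a mean of 0.50 (adjusted p = 0.000759, and adjusted p = 0.606 with an estimated correlation) to -0.11 (adjusted p = 0.0684). With the second 4-month white matter library left out instead, the means were 2.51 for interferon-stimulated genes, 2.54 for MHC class I, 6.29 for pericytes, 5.18 for endothelial cells and 1.78 for homeostatic genes, all of which passed at the preset correlation, and the smallest adjusted p among them was 0.391 with an estimated correlation. Endothelial genes had a mean of -0.20 and did not pass without the second 21-month white matter library (adjusted p = 0.476).

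With all 8 libraries edgeR called 0 genes in this comparison, 1316 had an unadjusted p under 0.05, DESeq2 called 427 and both limma fits called 0. With the first 4-month white matter library left out, edgeR called 1 gene, Spp1, which rose by 3.83 ± 0.35 (adjusted p = 0.0403), and without the second it called 4491. In the fit without the first library, Itgax differed by 3.65 ± 0.388 (adjusted p = 0.0688), Cst7 by 3.57, Lpl by 3.15, Apoe by 2.92, Clec7a by 2.60 and Axl by 2.03. P2ry12, Tmem119 and Cx3cr1 differed by -0.48, -0.46 and -0.09 there and by 0.19, 0.25 and 0.62 with all 8 libraries. In DESeq2 without that library, an alternative added after the data were seen, only the second library stood for 4-month white matter. In that fit Gpnmb rose by 4.71 ± 0.709, Mmp12 by 4.12 ± 0.694, Igf1 by 2.02 ± 0.522, Lgals3bp by 1.90 ± 0.342 and Csf1, a growth factor of microglia, by 1.78 ± 0.306. These 5 were chosen after their values were seen.

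Within grey matter, the mean log2 fold change of the disease-associated list was 0.010 and its median -0.093, with 11 of 30 genes above 0, and the test pointed down and did not pass (camera adjusted p = 0.579). Without the second 4-month grey matter library the mean was -0.22 with 24 of 30 below 0, and the list passed (adjusted p = 0.0436, and adjusted p = 0.884 with an estimated correlation). Apoe averaged 259.8 ± 17.7 CPM (SD, n = 2) at 21 months and 391.7 ± 183.1 at 4 months, Spp1 4.71 ± 0.34 and 2.31 ± 0.68, and Itgax 23.3 ± 5.28 and 14.2 ± 0.92. Homeostatic genes had a mean of -0.26 with 23 of 25 below 0 (adjusted p = 0.0236, and adjusted p = 0.934 with an estimated correlation), and did not pass when the first 4-month or the first 21-month grey matter library was left out (adjusted p = 0.407 and 0.18). Pericyte and smooth muscle genes had a mean of 1.30 with all 11 above 0 (adjusted p = 5.64e-06) and endothelial genes of 1.04 with 12 of 14 above 0 (adjusted p = 0.0019); the adjusted p of both was 0.934 with an estimated correlation. The pericyte sum was 144.9 and 833.2 CPM in the 4-month libraries and 1011 and 1211 in the 21-month ones. Its list had a mean of 0.64 with 9 of 11 above 0 and did not pass without the first 4-month grey matter library (adjusted p = 0.0838), and a mean of 2.99 without the second (adjusted p = 4.98e-06, and adjusted p = 0.857 with an estimated correlation). Red blood cell genes had a mean of -2.81 with all 8 below 0 (adjusted p = 1.32e-05, and adjusted p = 0.934 with an estimated correlation), and their sum was 26210 CPM in the first 4-month grey matter library and 1215 in the second; without the first the mean was 0.47 and the list did not pass (adjusted p = 0.674).

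No gene passed in grey matter with edgeR, where 119 had an unadjusted p under 0.05, and DESeq2 and both limma fits called 0. The 10 fixed genes differed by -0.60 for Tmem119 to 1.02 for Spp1, with an adjusted p of 1 for each. DESeq2 without the first 4-month white matter library called Ildr2, by 2.21 ± 0.397, and Vtn, a pericyte marker, by 1.70 ± 0.346, both higher at 21 months (adjusted p = 0.000808 and 0.0156) and both chosen after their values were seen.

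The difference between the aging changes of white and grey matter was tested last. The disease-associated list moved more in white matter, by a mean of 1.96 on the log2 scale with 28 of 30 members above 0 (camera adjusted p = 2.44e-28, and adjusted p = 0.455 with an estimated correlation). Adjusted over the list alone, 2 were called, and none over all genes. With the first 4-month white matter library left out the mean was 1.64 with all 30 above 0 (adjusted p = 2.75e-37, and adjusted p = 0.613 with an estimated correlation). Lysosome genes differed by a mean of 0.89 with 35 of 42 above 0 (adjusted p = 1.67e-09) and interferon-stimulated genes by 1.19 with 32 of 33 above 0 (adjusted p = 4.76e-11); the adjusted p of both was 0.455 with an estimated correlation. The means were 0.66 and 0.71 without that library and 1.41 and 2.42 without the second. Oligodendrocyte genes differed by -5.61 with all 16 below 0 (adjusted p = 6.04e-16, and adjusted p = 0.455 with an estimated correlation), and by -0.56 without that library.

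No single gene passed for this difference in edgeR's test, 455 had an unadjusted p under 0.05, DESeq2 called 39 and both limma fits called 0. Leaving out the second 4-month white matter library gave 2422 calls, and leaving out the first gave 0. Without the first, Apoe differed by 3.50 ± 0.589, Cst7 by 3.14, Itgax by 2.93 ± 0.452, Spp1 by 2.80, Clec7a by 2.46, Lpl by 2.13, Axl by 1.46, Tmem119 by 0.14, Cx3cr1 by 0.14 and P2ry12 by -0.08, with an adjusted p of 1 for each. In DESeq2 without that library, Apoe differed by 3.47 ± 0.532 and Itgax by 2.90 ± 0.574. In both of these fits only the second library stood for 4-month white matter.

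Across the 16237 tested genes, which are not independent replicates, the aging changes of white and grey matter correlated with Pearson's r of 0.222 and Spearman's rho of 0.267. The region differences at 4 and 21 months correlated with r of 0.31 and rho of 0.192. The comparisons set against each other share no library. The values of r were 0.0873 and 0.324 without the first 4-month white matter library.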

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

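All the tests of explanations here were chosen after the result they measure was seen in whole or in part, except the resampling of libraries to 1 depth, and the fit without the first 4-month white matter library was planned.

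For 19 lists the change with age differed between white and grey matter in the camera test of that difference at the preset correlation, and for none with an estimated correlation, where the smallest adjusted p was 0.455. The mean log2 difference, white minus grey matter, was 1.96 for disease-associated microglia, 1.16 for inflammatory genes, 1.19 for interferon-stimulated genes, 1.28 for MHC class I, 1.06 for MHC class II, 0.887 for lysosome, 1.24 for complement and Fc receptors, 0.757 for homeostatic microglia, 0.498 for ribosomal proteins, 0.82 for cholesterol efflux and 0.578 for immediate early genes. It was 2.36 for T cells, 1.04 for B cells, 1.06 for border-associated macrophages and 1.05 for endothelial cells. It was -5.61 for oligodendrocytes, -1.14 for cholesterol biosynthesis, -0.551 for the respiratory chain and -1.2 for ependymal and choroid plexus cells. With the first 4-month white matter library left out, 12 of the 19 passed with the same sign and 3 had the other sign. Of these 3 the respiratory chain passed in the opposite direction (0.42, adjusted p = 0.00028, and adjusted p = 0.746 with an estimated correlation), while cholesterol biosynthesis (0.251) and B cells (-0.112) did not pass. Another 4 kept their sign and no longer passed, homeostatic microglia (0.135), immediate early genes (0.169), border-associated macrophages (0.864) and endothelial cells (0.335). Of the 12, the mean moved to 0.377 for inflammatory genes, 0.706 for interferon-stimulated genes, 0.664 for MHC class I, 0.443 for MHC class II, 1.46 for cholesterol efflux and -0.561 for oligodendrocytes. With any 1 of the 8 libraries left out, 8 of the 19 passed with the same sign each time. These were disease-associated microglia (1.63 to 2.79), inflammatory genes (0.377 to 2.48), interferon-stimulated genes (0.706 to 2.42), MHC class I (0.664 to 2.56), MHC class II (0.443 to 2.6), lysosome (0.66 to 1.41), complement and Fc receptors (0.856 to 2.16) and oligodendrocytes (-7.2 to -0.561). For the other 11 the call ended, or for the respiratory chain reversed, without at least 1 library. Over the 8 fits their means ranged from 0.135 to 2.04 for homeostatic microglia, 0.0796 to 0.826 for ribosomal proteins, 0.286 to 1.46 for cholesterol efflux, 0.169 to 1.31 for immediate early genes, -1.75 to 0.251 for cholesterol biosynthesis, 1.02 to 4.45 for T cells and 0.196 to 2.57 for border-associated macrophages. They ranged from -0.986 to 0.42 for the respiratory chain, -0.113 to 3.26 for B cells, -3.84 to 0.00814 for ependymal and choroid plexus cells and -1.24 to 4.14 for endothelial cells. The number that passed with the same sign was 12 and 14 without the first and the second 4-month white matter library, 14 and 16 for those of 4-month grey matter, 16 and 17 for 21-month white matter and 19 and 14 for 21-month grey matter.

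The first 4-month white matter library stood apart. All 16 tested oligodendrocyte genes were highest in it, which is what RNA of oligodendrocytes or myelin in the sample would give, despite the gradient against myelin and the CD11b beads. These markers had already set the library apart, so this was no independent test. Depth and the pair of most abundant transcripts were argued against as the cause, since with these left out and every library resampled with replacement to 2741239 counts its highest r with another library was 0.748, below the lowest of 0.837 among the other 7. A wrong label on a library of 21-month white matter was argued against, since relative to the sum of P2ry12, Tmem119 and Cx3cr1 all 7 of the disease-associated genes fixed in advance lay below both libraries of that group; a wrong label on a grey matter library stays open, since its neutrophil sum over the same 3 genes, 0.372, lay between the highest of the other white matter libraries (0.28) and the lowest of grey matter (0.523). No biological explanation was tested, since the partner library of its group did not share the pattern.

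Neutrophil and monocyte genes were lower in white matter. Blood carried along with grey matter stays open. Over the 4 grey matter libraries the log2 range of the neutrophil sum was 0.197 of that of the red blood cell sum (1.01 against 5.15). Both sums were highest in the first 4-month grey matter library, at 5483 and 26210 CPM. Between white and grey matter libraries of the same replicate number, both were higher in grey matter at each age. Beads against CD11b can change the mix of blood cells, so unequal ranges cannot decide the question. A lower share of microglia in grey matter samples could not be decided from the marker sums of 4 other cell types. Between single 21-month libraries the lowest log2 difference was -0.733 for endothelial cells and -0.81 for pericytes. It was 0.26 for oligodendrocytes and -1.2 for astrocytes. The highest was -1.44 for neutrophils, which all 4 fell short of. For monocytes it was -1.08, which 3 of the 4 fell short of and astrocytes did not. The beads select myeloid cells, so these 4 types need not move alike with neutrophils and monocytes. Homeostatic microglia sums overlapped between the regions at 21 months, at 28790 and 27580 CPM in white matter and 27120 and 31600 in grey matter. The 12 neutrophil genes differed by a mean of -3.11 with an SD of 0.939, so fewer granulocytes among the CD11b-positive cells of white matter may be a candidate explanation. Whether this reflects the tissue or its dissection stays open.

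Disease-associated genes were higher in aged white matter. More border-associated macrophages or monocytes were argued against by mean log2 fold changes of -1.12 and -2.14 for their lists in the 21-month libraries (-2.10 for the former with all 8 but the second library of 21-month white matter). RNA of astrocytes was argued against by a mean of -0.646 with 2 of 12 markers above 0. That mean was -1.88 to -0.254 with all 8 but any 1 of the 21-month libraries. Against the disease-associated median of 1.03, the immediate early and heat shock list had a median of 0.0253, with an SD of 0.559 over its members. This argued against genes induced by dissociation only as far as that list stands for them. Its mean was 0.0943 with 14 of 26 above 0, Dusp2 was the only member called (1.494, adjusted p = 0.0255), and with all 8 but the second 21-month white matter library the list passed at 0.347 (adjusted p = 0.00469, and adjusted p = 0.716 with an estimated correlation; median 0.235 against 1.24), so a smaller part for dissociation is not excluded. An effect of aged white matter on microglia may underlie the pattern, as a hypothesis found and tested on the same data, and only with the preset correlation did the list pass.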

How the results depend on the processing

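Voom with quality weights and DESeq2 without the first 4-month white matter library were chosen after the data were seen. The count of called genes was 0 in all 5 comparisons with all 8 libraries and stayed 0 with RLE scaling, library size only, at least 10 counts in every library, limma on the deposited values and, where run, the log2 minimum, which was not run for age by region. Library size alone put the median log2 fold change at 0.294 for white matter aging, -0.177 at 4 months, 0.143 for age by region and 0.126 for grey matter aging. DESeq2 called 47, 587, 427 and 39 genes at 21 months, at 4 months, for aging in white matter and for age by region; without a low-count filter edgeR called 147, 1113, 963 and 470, and 17 for aging in grey matter. The 4 libraries of the 21-month comparison alone gave 232 calls, and quality weights 123; both gave 0 in the other comparisons they were run for. DESeq2 without the first 4-month white matter library gave 165, 19, 23, 2 and 2 in the order 21 months, 4 months, white matter aging, grey matter aging and age by region. The unfiltered calls were tested on more genes of low count; the cause of the other differences was not tested. With each library left out, the counts ranged from 0 to 19, 0 to 4222, 0 to 4491 and 0 to 2422 in the same first 4 comparisons without grey matter aging, which stayed at 0. A group left with 1 library is assumed to vary like the others.

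The number of lists past the threshold fell to 0 in every comparison with an estimated correlation and with fry; at 4 months it was 23, and between 12 and 24 with a library left out. The correlation of aging changes ranged from 0.0154 to 0.272 and that of region differences from 0.0383 to 0.324 with a library left out, and was 0.145 and 0.211 with at least 10 counts in every library. The replicate block gave 0 called genes in all 5 comparisons, as did a block within age in 3, and 1 of 166 named genes and lists changed sign under it. Same-number deviations correlated at 0.399 for the 4-month groups, 0.0632 for the 21-month groups and -0.145 to 0.161 between ages. The numbers were not taken to pair samples. Red blood cell sums were higher, and pericyte sums lower, in the first library of every group. For red blood cells they were 7310 against 614.8 CPM in 4-month and 753.6 against 203.6 in 21-month white matter. In grey matter they were 26210 against 1215 and 2667 against 736.3. Whether libraries of the same number share animals or a preparation is not stated. These sums and the correlation at 4 months leave it open.

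All 1172 values of genes named for the 21-month region comparison kept their sign. Apart from the genes fixed in advance, these were named because they were called in that comparison, so a change of sign was unlikely from the start. At 4 months with a library left out, Apoe ranged from -0.027 to 0.96, Cst7 from -1.84 to 0.26, Clec7a from -1.83 to 0.043, Itgax from -1.73 to 0.079 and Axl from -1.84 to 0.91. Axl was -0.047 with the block, -0.34 with the block within age, -0.35 with limma on the deposited values and -0.27 with quality weights. DESeq2 without the first library gave 0.057 for Clec7a and 0.092 for Itgax. For aging in white matter P2ry12 ranged from -0.48 to 1.44, Tmem119 from -0.46 to 1.67 and Cx3cr1 from -0.086 to 2.04, with -0.49, -0.47 and -0.10 by that DESeq2 fit. For aging in grey matter Cst7 ranged from -0.22 to 1.47 and Clec7a from -0.75 to 0.64. For age by region P2ry12 ranged from -0.083 to 1.85 and was -0.11 by that DESeq2 fit.

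Of the list means with a library left out, at 21 months oligodendrocytes ranged from -0.24 to 0.40. At 4 months disease-associated genes ranged from -0.98 to 0.19, cholesterol efflux from -0.062 to 1.11 and inflammatory genes from -1.91 to 0.19. For aging in white matter homeostatic genes ranged from -0.11 to 1.78, monocytes from -0.36 to 1.04 and border-associated macrophages from -0.78 to 1.59. For aging in grey matter disease-associated genes ranged from -0.22, where the list passed, to 0.35, neutrophils from -0.94 to 0.050, monocytes from -0.14 to 0.74, cholesterol efflux from -0.44 to 0.38, interferon-stimulated genes from -0.21 to 0.44, inflammatory genes from -0.10 to 0.46 and oligodendrocytes from -1.16 to 0.79. For age by region neutrophils ranged from -1.56 to 0.51 and monocytes from -0.64 to 0.87. The cause was not tested.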

Other observations

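The list and gene tests here were planned; the use of the 21-month libraries alone to name genes and the choice of levels in the last paragraph came after the results were seen. At 21 months, ribosomal protein genes lay higher in white matter, with a mean log2 fold change of 0.31 and 73 of 85 above 0 (camera adjusted p = 6.72e-05, and adjusted p = 0.623 with an estimated correlation). Their sums overlapped, at 3613 and 2831 CPM in white matter and 2296 and 2868 in grey matter. The list did not pass without the first 21-month library of white matter (mean 0.085, adjusted p = 0.485) or of grey matter (0.20, adjusted p = 0.0515), and the mean was 0.47 without the second of grey matter and 0.46 without the second of white matter. The nuclear-encoded respiratory chain had a mean of 0.37 with 63 of 80 above 0 (adjusted p = 0.0011, and adjusted p = 0.709 with an estimated correlation), and 0.23 without the second 21-month white matter library. T cell genes had a mean of 1.72 with 4 of 5 above 0 (adjusted p = 0.00117, and adjusted p = 0.375 with an estimated correlation), and their sums were 25.8 CPM in both 21-month white matter libraries and 20.01 and 7.26 in grey matter. Without the second 21-month grey matter library the mean was 0.76 and the list did not pass (adjusted p = 0.244), and it was 4.09 without the first of grey matter and 0.996 without the second of white matter. Cd22, a lectin in the B cell list, rose by 1.33 ± 0.266 in the 21-month libraries (adjusted p = 0.0415) and Nes by 1.66. Cd24a and Vcan had log2 fold changes of -2.54 and -2.13. Each of these genes passed in edgeR's test on the 21-month libraries alone, while the fit of all 8 libraries called no gene. The sum of the B cell list was not higher in 21-month white matter, at 427.9 and 405.3 CPM against 430.4 and 504.1 in grey matter. MHC class II genes had a mean of -0.63 with 4 of 10 above 0 (adjusted p = 0.00317, and adjusted p = 0.564 with an estimated correlation), and proliferation genes of -0.44 with 7 of 25 above 0 (adjusted p = 0.00431, and adjusted p = 0.454 with an estimated correlation). Both calls depended on single libraries, though between libraries of the same replicate number the sums of both lists were higher in grey matter. The MHC class II sums overlapped, at 1360 and 857 CPM in white matter and 2536 and 1201 in grey matter, and the list did not pass without the first 21-month grey matter library (-0.24, adjusted p = 0.284) or the second of white matter (-0.37, adjusted p = 0.328), while its mean was -0.99 without the first of white matter. The proliferation sums were 290.7 and 274.4 CPM in white matter and 294.5 and 405.3 in grey matter. That list did not pass without the second 21-month grey matter library (-0.17 with 13 of 27 above 0, adjusted p = 0.302), and its mean was -0.73 without the first of grey matter and -0.67 without the second of white matter.

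Spp1 and Lpl stood at 21.8 and 30.4 CPM in the second 4-month white matter library, above 2.79 and 5.67, the higher values of 4-month grey matter. Apoe and Itgax in that library, at 499.7 and 14.8, lay within or beside the grey matter values of 521.1 and 262.2 for Apoe and 14.8 and 13.5 for Itgax.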
